A study of Mus musculus with 18 samples.

How the data were processed

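RNA of 18 mouse samples was extracted with TRIzol, labelled with Cy5 and hybridised to one-colour arrays, per the labels' protocols. The labels give 7 fibroblast, 5 induced cardiomyocyte and 6 heart cardiomyocyte arrays. The deposited table holds 1 linear probe intensity per array for 26423 probes. Each array has a median intensity of 185 or 186, a lower quartile of 53 or 54 and an upper quartile of 855 to 856, so the authors deposited intensities that had already been brought to nearly 1 common distribution. The scanner, the background correction and the normalization method are not given in the sources used here. A common distribution forces the arrays to have the same median, so a change of total RNA per cell cannot be seen. Between 302 and 689 probes per array are listed at 0, about 23.2% to 23.6% lie under 50, and the brightest probes end near 65482, where they are saturated.

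Intensities were floored at 1 and taken to log2, with no further normalization. The median SD of repeat arrays of 1 preparation was 1.19 on the log2 scale for probes with a mean of up to 10 and 0.87 up to 25. For that reason a group mean under 50 was read as a bound, a choice made after the values were seen: each array's value under 50 is then set to 50 before the arrays are averaged, the fold between these means is written as at least that fold, and no fold is given where both means lie under 50. Probes were named through the platform annotation supplied with the table, updated to current symbols. Of the 26423 probes, 20377 have 1 symbol and 6046 have none here. Of those with a symbol, 18213 matched a current symbol, 2126 matched through a synonym and 38 kept the platform's name. For the 2278 genes with more than 1 probe, the probe with the highest mean over the 18 arrays stood for the gene, which left 17742 genes. Table columns without a sample numbered 0.

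The assignment of arrays to preparations was set from the labels before the data were examined. The labelling protocol lists 6 preparations, and the titles number arrays within them, so arrays of 1 preparation were taken as repeat hybridisations and averaged. The labels do not state this outright. Fibroblast titles 1, 2 and 3 carry no preparation number and were assigned to preparation 1. Fibroblast 7 and heart 3-3 fall in none of the 6 and were kept for alternatives only. Heart arrays 1-1 and 1-2, whose probes differ by a median of 1 unit, were averaged first and counted as 1 array, a choice made after the values were seen. The labels give no batch, slide or scan date, so a batch that went with a group could not be told apart from it.

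The comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on intensity) with the 3 groups in 1 model. The 6 preparations leave 3 residual degrees of freedom, to which the moderated variance adds 6.71 prior degrees. Tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over all 26423 probes, with a call at an adjusted p under 0.05. A fixed set of 27 gene lists covering heart functions, metabolism, cell types of skin and heart, stress and cell division was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera called 10 lists for induced cells against fibroblasts, 12 for heart cells against fibroblasts and 11 for induced against heart cells. With a correlation estimated from the data, 0 lists passed in any of the comparisons. Whether that setting can detect a shifted list with 3 residual degrees of freedom was not measured. The count of members adjusted over the list alone applies Benjamini-Hochberg within the list. All counts of members refer to the listed genes that were measured.

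The genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and falls per comparison among called genes whose arrays do not overlap, the 3 most changed called members of each called list, and a panel of 31 genes of heart, fibroblasts and pluripotency, of which 21 were measured. Predicted genes and clone names were skipped. Named genes outside the rule are marked as such.

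The procedure was tested on simulated data with 200 changed genes among 17742. Of 2-fold changes it recovered 6% for induced cells against fibroblasts, 2% for heart cells against fibroblasts and 4% for induced against heart cells. Of 4-fold changes it recovered 74%, 65% and 69%, and the false calls made up 8%, 4.2% and 3.8% of all calls. With so few changed genes the Benjamini-Hochberg cutoff was stricter than in the data, where 8126, 8331 and 2997 genes were called. These rates therefore hold for the simulation only. How many 2-fold differences were missed in the data was not measured. The alternatives covered the treatment of repeat arrays and of the unplaced arrays, a replicate block, other scalings, a filter on dim probes, a fold threshold, the variance model, an offset or a higher floor, other probes of a gene, and leaving out each preparation and array in turn. No genome was given, so no coordinates are reported.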

Results

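Gene expression was measured on 18 one-colour arrays, each carrying Cy5-labelled RNA of newborn mice of the ICR stock. Per the labels, 7 arrays hold fibroblasts, 5 hold cardiomyocytes induced from fibroblasts and 6 hold cardiomyocytes taken directly from newborn heart. The fibroblasts came from collagenase-digested skin of mice under 3 days old after the epidermis was removed. The titles of all 7 fibroblast arrays read cultured, 2 of them for 8 days, whereas the heart cells are labelled as taken directly from the heart. Culture therefore cannot be told apart from cell type between these groups. How the cells were induced is not given in the sources used here, and the tissue label reads skin for all samples, heart included. The labels name 6 preparations, 2 per group. Arrays of 1 preparation were averaged, so n = 2 preparations per group in every comparison. Nothing in the labels says that the preparations came from separate animals or cultures, so the p-values measure only the spread between these preparations, which can be technical.

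Fibroblast 7 and heart 3-3 belong to none of the listed preparations and took no part in the comparisons. Heart arrays 1-1 and 1-2 had a median difference of 1 intensity unit per probe, against 24 to 42 for the 13 other pairs of repeat arrays, and were counted as 1 array. The number of arrays limits the precision. Repeat arrays differed by a median SD of 0.17 on the log2 scale for the brightest probes and 0.55 for probes between intensities of 25 and 50. Levels under an intensity of 50 are therefore treated as a bound, and a change against such a level is given as at least a stated fold.

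Arrays of 1 group resembled each other more than those of other groups, with 1 exception. Principal component 1 held 45.7% of the variance over the 18 arrays and component 2 held 22.1%. The array labelled fibroblast 7 had a Pearson correlation across probes of 0.978 with the mean of induced preparation 1, but only 0.860 and 0.830 with the means of the fibroblast preparations. Actc1, the cardiac alpha-actin gene, stood at 34589 on fibroblast 7 and at 286 to 354 on the other 6 fibroblast arrays. Heart 3-3 correlated at 0.972 with heart preparation 2.

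**Figure D1:**
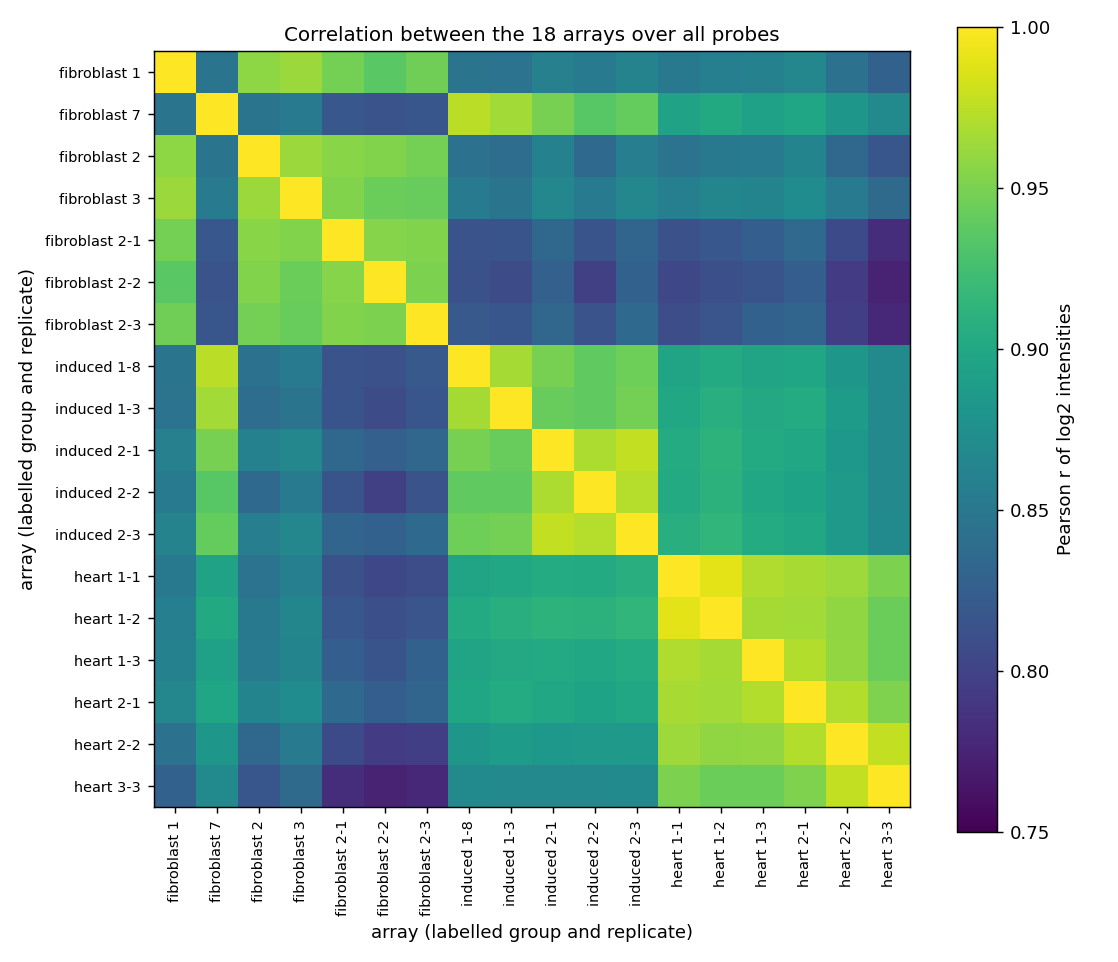
Pearson correlation of log2 intensities over 26423 probes between each pair of the 18 arrays, with arrays on both axes in the order of their labelled groups and colour giving r. The array labelled fibroblast 7 correlates at 0.974 with induced 1-8 and at 0.846 with fibroblast 1.

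How the induced cells differed from fibroblasts is the question of the comparison between the 2 groups. Genes of the muscle sarcomere were far higher in the induced cells, most genes of skeletal muscle and adipocytes were higher, and most genes of endothelial cells, macrophages and keratinocytes were lower. Actc1 rose from a mean intensity of 310.8 to 30739, a log2 change of 6.63 (SE 0.30, n = 2 preparations per group, limma adjusted p = 2.59e-06). Tnnt2, which encodes cardiac troponin T, rose from 283.7 to 11380 (log2 change 5.33, SE 0.35). Tnni2, which encodes the troponin I of fast skeletal muscle, rose from 1207 to 40465 (log2 change 5.07, SE 0.32, adjusted p = 7.72e-06). C1qa, a complement gene of macrophages, fell from 6315 to 110.2 (log2 change -5.84, SE 0.31).

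Of 28 listed genes of the cardiac sarcomere, 15 were measured. All 15 were called higher in induced cells, and all 15 when adjusted over the list alone. Their median log2 change was 5.33, with a camera adjusted p of 3.35e-12 and an adjusted p = 0.27 with an estimated correlation. Ankrd1, a titin-associated ankyrin repeat protein of muscle, rose at least 242-fold to 12672. Smpx, a small muscle protein, rose at least 159-fold to 8054, and Csrp3, a LIM protein of the muscle Z-disc, rose 139-fold from 64.2. Tnni3, the troponin I of heart muscle, is among the 15 with means of only 16.6 and 32, both under 50 (adjusted p = 0.0487, and 0.0710 without fibroblast preparation 1).

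The skeletal muscle list, with 13 of its 24 genes measured, moved with the sarcomere list. Of the 13, 11 were higher and 0 lower, with the same counts adjusted over the list alone (median 3.53, camera adjusted p = 9.34e-08, adjusted p = 0.27 with an estimated correlation). Actn3, the alpha-actinin of fast fibres, rose 40.6-fold from 71.4 to 2898, and Tnnt3, the fast skeletal troponin T, rose 23.9-fold to 17464. Of the 18 cardiac secreted peptides and other cardiac markers, 11 were higher and 3 lower, likewise adjusted over the list alone (median 3.28, camera adjusted p = 0.00039, adjusted p = 0.28 with an estimated correlation). Cox8b, a muscle subunit of cytochrome oxidase, rose 73.9-fold and Ckm, the creatine kinase of muscle, rose 64.5-fold to 8321. Ckm measured 14755 in induced preparation 1 and 4693 in induced preparation 2. Ckmt2, the mitochondrial creatine kinase of striated muscle, rose at least 77.2-fold to 3859 by a probe that is near 0 in the fibroblasts. The natriuretic peptide genes went the other way: Nppa fell by 1.45 on the log2 scale to 87.8 (SE 0.34, adjusted p = 0.00796) and Nppb fell by 2.51 to 226.5 (SE 0.33).

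Many, though not all, genes of energy metabolism were higher in the induced cells. Of 28 oxidative phosphorylation genes, 18 were higher and 2 lower, or 19 and 3 adjusted over the list alone (median 1.12, camera adjusted p = 7.15e-05, adjusted p = 0.27 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, rose 12.6-fold to 8062. Of 20 fatty acid oxidation genes, 11 were higher and 1 lower, or 12 and 1 adjusted over the list alone (median 1.41, camera adjusted p = 8.93e-05, adjusted p = 0.27 with an estimated correlation), among them Acsl1, a long-chain acyl-CoA synthetase, at 19.1-fold. Glycolysis had 8 of 14 members higher and 0 lower, with the same counts adjusted over the list alone (median 0.70, camera adjusted p = 0.00113, adjusted p = 0.27 with an estimated correlation), led by Pfkm, the muscle phosphofructokinase, at 17.2-fold. Of 18 adipocyte genes, 12 were higher and 1 lower, or 13 and 1 adjusted over the list alone (median 1.91, camera adjusted p = 0.000367, adjusted p = 0.27 with an estimated correlation). Cfd, the secreted factor adipsin, rose 107-fold to 17622 and Car3, a carbonic anhydrase of fat and muscle, rose 106-fold to 49644. Thrsp, a lipogenic gene, rose at least 374-fold to 18682. Ucp1, the uncoupling protein of brown fat, fell at least 1.42-fold, from 68.9 to a level under 50. Ucp1 was dim in fibroblasts already, at 97.5 in preparation 1 and 48.7 in preparation 2.

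Endothelial, macrophage and keratinocyte genes were mostly lower in the induced cells. None of the 18 endothelial genes were higher and 15 were lower, or 16 adjusted over the list alone (median -2.61, camera adjusted p = 3.42e-08, adjusted p = 0.27 with an estimated correlation); Robo4, an endothelial receptor, fell 26.7-fold and the tight junction gene Cldn5 fell 22.2-fold. Of 18 macrophage and leukocyte genes, 1 was higher and 16 were lower, or 2 and 16 adjusted over the list alone (median -2.93, camera adjusted p = 3.63e-07, adjusted p = 0.27 with an estimated correlation). Of 25 keratinocyte and epithelial genes, 1 was higher and 15 were lower, or 1 and 16 adjusted over the list alone (median -2.04, camera adjusted p = 2.34e-06, adjusted p = 0.27 with an estimated correlation). Sfn, the epidermal 14-3-3 sigma gene, fell 81.2-fold from 56603 to 697.1. The mast cell protease gene Cpa3 fell 369-fold from 25953, and Hdc, the histidine decarboxylase of mast cells, fell at least 67.9-fold. Hspa1a, an inducible heat shock protein, fell 202-fold from 51984, and Ccn2, a target of transforming growth factor beta, fell 107-fold from 31744. Sfn and Cpa3, genes of other skin cells, were thus bright in the fibroblast samples. The cell make-up of the samples was not measured. In any of the comparisons an effect on expression therefore cannot be told apart from a difference in cell make-up.

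The fibroblast and extracellular matrix list did not shift as a whole: of 40 genes, 12 were higher and 11 lower, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.956). Postn, which encodes a matrix protein of fibroblasts, measured 29889 in fibroblasts and 28783 in induced cells (log2 change -0.05, SE 0.22, adjusted p = 0.864). Vim was close to the top of the scale in all groups and gives no measure of change. Of 19 cardiac transcription factors, 4 were higher and 6 lower, also adjusted over the list alone (median -0.55, camera adjusted p = 0.675). Mef2c, a factor of both heart and skeletal muscle, rose 9-fold to 7035, by a probe whose alternative gave a log2 change of 0.67 that was not called (adjusted p = 0.16). Gata4 fell by 1.69 on the log2 scale to 755.3 (adjusted p = 0.00368), and Hand2 measured 149.9 and 83.1 (adjusted p = 0.1). The pluripotency genes Pou5f1 (243.9 and 408.3), Sox2 (140.8 and 81.9) and Klf4 (7944 and 5371) were not called.

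Across the 17742 genes, 8126 were called (45.8%), 3999 higher and 4127 lower, of which 3661 and 3652 changed at least 2-fold. Without fibroblast preparation 2 the count was 4539. With fibroblast 7 and heart 3-3 taken as 1 added preparation each of their labelled groups, only 5 genes were called.

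**Figure D2:**
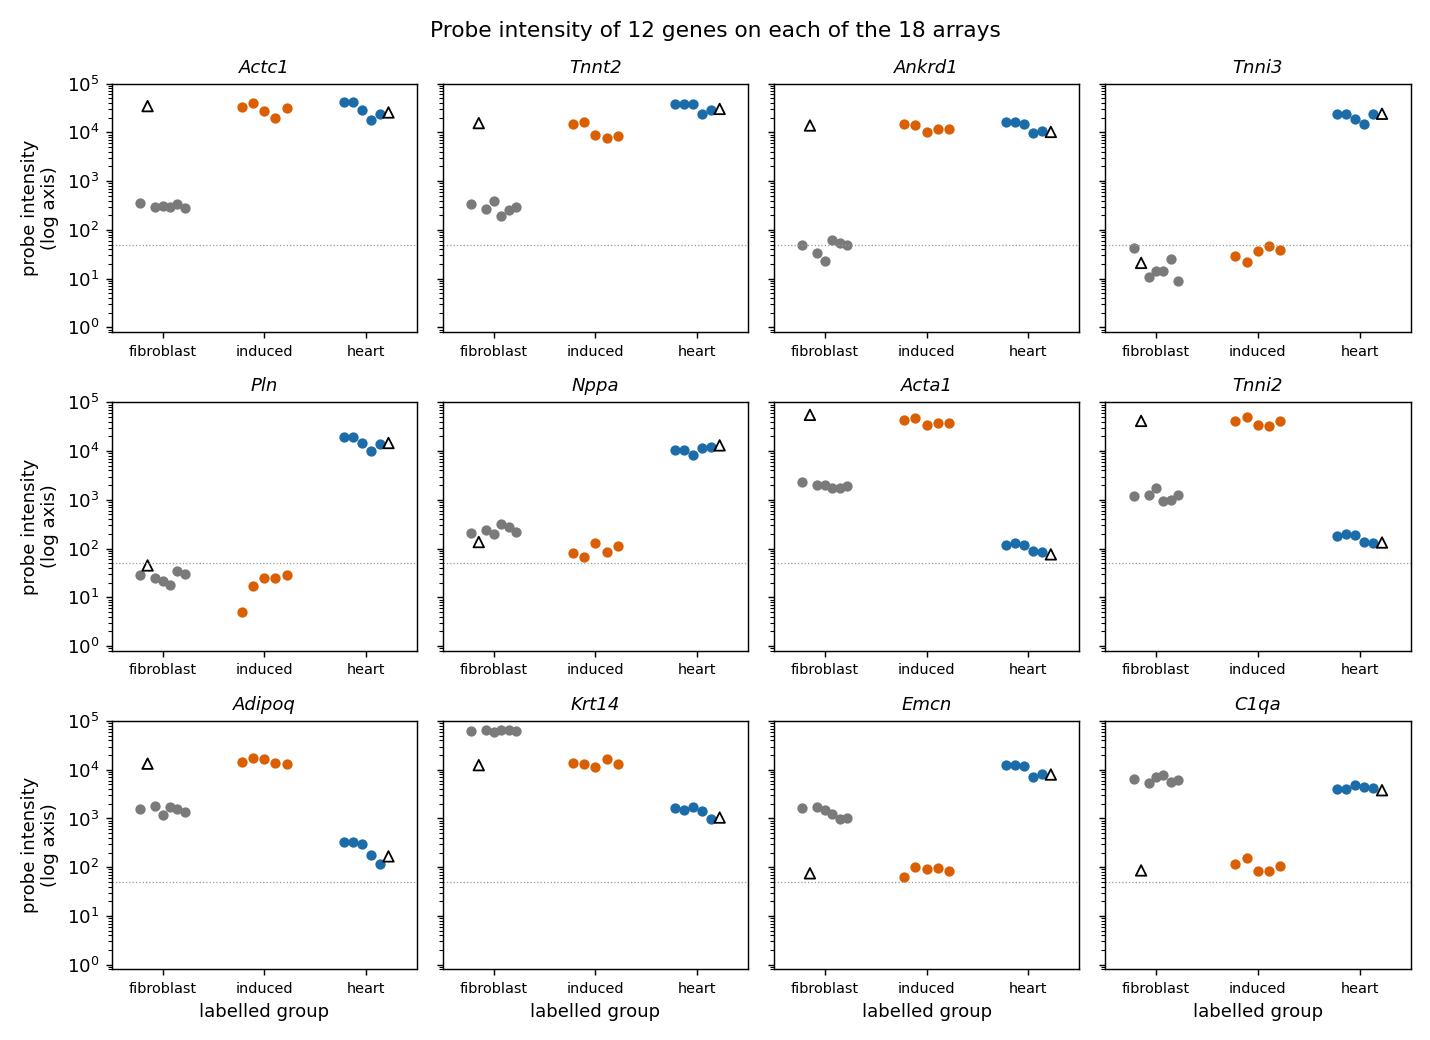
Probe intensity (log axis) of 12 genes on each of the 18 arrays by labelled group; filled points are arrays of the listed preparations, open triangles are fibroblast 7 and heart 3-3, and the dotted line marks an intensity of 50. Tnni3 lies under 50 on the fibroblast and induced arrays against a heart mean of 19990, while Acta1 has a mean of 40614 in the induced cells and 102.4 in the heart cells.

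The comparison of heart cells with fibroblasts gives the distance between the starting cells and the cells named as the aim of the series, with culture not told apart from cell type. Heart cells had far higher levels of sarcomere genes and of most genes on the list of secreted peptides and other cardiac markers, and lower levels of most keratinocyte genes, while the calcium handling, matrix and skeletal muscle lists shifted with only part of their members called (adjusted p = 0.56 each with an estimated correlation). Tnni3 rose at least 400-fold, from 16.6 to 19990 (adjusted p = 6.46e-07). Pln, which encodes the calcium pump inhibitor phospholamban, rose at least 284-fold from 25.9 to 14223 (adjusted p = 3.04e-06). Nppa, the atrial natriuretic peptide gene, rose 43.5-fold to 10448 (log2 change 5.44, SE 0.34, adjusted p = 8.12e-06). Sfn fell 269-fold to 210.8 (log2 change -8.07, SE 0.39).

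All 15 sarcomere genes were higher in heart cells, also adjusted over the list alone (median 4.78, camera adjusted p = 9.94e-13, adjusted p = 0.31 with an estimated correlation), with Tnnt2 at 31440 and Actc1 at 26737. Of the 18 cardiac secreted peptides and other markers, 16 were higher and 1 was lower, also adjusted over the list alone (median 4.32, camera adjusted p = 5.34e-09, adjusted p = 0.31 with an estimated correlation); Popdc2, a membrane protein of striated muscle, rose 91.9-fold and Cox6a2, a muscle subunit of cytochrome oxidase, rose 51.3-fold. Their other probes gave smaller log2 changes, 5.79 (adjusted p = 3.96e-05) and 1.51 (adjusted p = 0.0588) for Popdc2 and 1.77 (adjusted p = 0.00199) for Cox6a2. Calcium handling and excitability genes had 13 of 26 members higher and 4 lower, also adjusted over the list alone (median 1.02, camera adjusted p = 0.016, adjusted p = 0.56 with an estimated correlation). Kcnj5, an atrial potassium channel gene, rose at least 34.4-fold, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose 20.3-fold to 22665; its 2 other probes gave a log2 change of 6.16 (adjusted p = 0.000615) and one of -0.32 that was not called. Oxidative phosphorylation genes were higher for 20 and lower for 2 of 28, or 21 and 2 adjusted over the list alone (median 1.17, camera adjusted p = 0.000175, adjusted p = 0.31 with an estimated correlation). Fatty acid oxidation genes were higher for 12 and lower for 3 of 20, also adjusted over the list alone (median 1.01, camera adjusted p = 0.00649, adjusted p = 0.48 with an estimated correlation), with Acadm, the medium-chain dehydrogenase, at 6.23-fold. Of 14 glycolysis genes, 8 were higher and 1 was lower, or 9 and 1 adjusted over the list alone (median 0.73, camera adjusted p = 0.0372, adjusted p = 0.47 with an estimated correlation). Hand2 rose 5.66-fold to 848.2, whereas Gata4 measured 2432 and 3292 (adjusted p = 0.327) and Mef2c 781.5 and 1146 (adjusted p = 0.226).

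Keratinocyte and epithelial genes were lower for 19 and higher for 1 of 25, also adjusted over the list alone (median -3.71, camera adjusted p = 5.43e-10, adjusted p = 0.31 with an estimated correlation); Krt17, a keratin of basal epidermis and hair follicles, fell 130-fold from 54512. Of 40 fibroblast and matrix genes, 22 were lower and 4 higher, or 23 and 4 adjusted over the list alone (median -0.84, camera adjusted p = 0.00117, adjusted p = 0.56 with an estimated correlation). Serpinf1, a secreted serpin, fell 15-fold, and Tcf21, a factor of epicardial and fibroblast precursors, rose 89.7-fold from 52.4 to 4700. Skeletal muscle genes were lower for 5 and higher for 0 of 13, also adjusted over the list alone (median -0.59, camera adjusted p = 0.045, adjusted p = 0.56 with an estimated correlation); Acta1, the skeletal alpha-actin gene, fell 19.0-fold from 1943 to 102.4. Melanocyte, Schwann and neural genes were lower for 7 and higher for 2 of 15, also adjusted over the list alone (median -0.74, camera adjusted p = 0.0372, adjusted p = 0.47 with an estimated correlation), with Pmel, a melanosome gene, down 47.0-fold by a probe whose alternative gave a log2 change of only -1.04 (adjusted p = 0.0232). Some macrophage and endothelial markers were higher in heart cells: 8 of 18 macrophage genes were higher and 0 lower, also adjusted over the list alone (median 0.77, camera adjusted p = 0.016, adjusted p = 0.47 with an estimated correlation). Endothelial genes were higher for 9 and lower for 2 of 18, or 10 and 2 adjusted over the list alone (median 1.11, camera adjusted p = 0.045, adjusted p = 0.63 with an estimated correlation), with the cadherin gene Cdh5 up 9.03-fold to 11748. Cdh5 read 17597 to 19248 on the arrays of heart preparation 1 and 8222 and 6800 on those of heart preparation 2.

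Serinc1 and Csnk1a1 fell at least 749-fold and 84.7-fold, from 37465 and 4717, by probes whose mean is near 0 in the heart group alone. Csnk1a1 read 119 on heart 1-2 and 6 on heart 1-1. In all, 8331 genes were called, 4259 higher and 4072 lower in heart cells. The count was 4649 without fibroblast preparation 2, 5368 without heart preparation 1, 5240 without heart preparation 2 and 2133 with fibroblast 7 and heart 3-3 as added preparations. Without fibroblast preparation 1 the calls of the glycolysis, skeletal muscle, endothelial and melanocyte lists were lost (adjusted p = 0.0854 each), as were that of the macrophage list with the mean of all probes of a gene (adjusted p = 0.0569) and that of the skeletal muscle list without the dimmest probes (adjusted p = 0.0663).

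How near the induced cells came to cells of the heart is the question of the remaining comparison. The sarcomere and oxidative phosphorylation lists were not called as different, but several genes of heart muscle were far lower in the induced cells and most skeletal muscle genes were higher. Pln measured 15.6 in induced and 14223 in heart cells, at least 284-fold lower (adjusted p = 2e-06), and Tnni3 measured 32 and 19990, at least 400-fold lower (adjusted p = 6.73e-07). Nppa was 119-fold lower at 87.8 against 10448 (log2 change -6.89, SE 0.34, adjusted p = 3.07e-06). Acta1 was 397-fold higher at 40614 against 102.4 (log2 change 8.63, SE 0.31, adjusted p = 5.51e-07).

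Of the 15 sarcomere genes, 4 were higher and 2 lower than in heart, or 5 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.72); its median of 0.29 and mean of -0.33 differ in sign. Actc1 differed by 0.20 on the log2 scale (SE 0.30, adjusted p = 0.719), while Tnnt2 was 2.76-fold lower (adjusted p = 0.0198, and 0.171 without heart preparation 1). The oxidative phosphorylation list had 1 of 28 genes lower and 0 higher, or 0 and 0 adjusted over the list alone (median -0.07, camera adjusted p = 0.758). Of 13 skeletal muscle genes, 10 were higher and 0 lower, also adjusted over the list alone (median 3.88, camera adjusted p = 1.52e-15, adjusted p = 0.2 with an estimated correlation); Tnni2 was 253-fold and Tnnc2, the fast troponin C, 179-fold higher. Atp2a1, the calcium pump of fast skeletal muscle, was at least 498-fold higher at 26297. Calcium handling genes were lower for 12 and higher for 3 of 26, or 14 and 5 adjusted over the list alone (median -0.80, camera adjusted p = 0.00172, adjusted p = 0.44 with an estimated correlation), with Kcnq1, a repolarising potassium channel gene, down 7.15-fold. Of the 18 cardiac secreted peptides and other markers, 8 were lower and 4 higher, also adjusted over the list alone (median -0.66, camera adjusted p = 0.0498, adjusted p = 0.46 with an estimated correlation); this call was lost without heart preparation 1 (adjusted p = 0.136). Mb, the myoglobin gene, was 23.3-fold lower at 686.9, and its other probe, at 35.4 and 78.2, was not called.

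Endothelial and macrophage genes were nearly all lower in the induced than in the heart cells. All 18 endothelial genes were lower, also adjusted over the list alone (median -3.62, camera adjusted p = 1.81e-19, adjusted p = 0.2 with an estimated correlation); Emcn, an endothelial sialomucin, was 114-fold lower at 85.2. Of 18 macrophage genes, 17 were lower and 0 higher, also adjusted over the list alone (median -3.65, camera adjusted p = 4.76e-19, adjusted p = 0.12 with an estimated correlation), and Ctss, the protease cathepsin S, was at least 73.5-fold lower. Smooth muscle and myofibroblast genes were lower for 8 and higher for 2 of 13, also adjusted over the list alone (median -1.92, camera adjusted p = 0.000506, adjusted p = 0.2 with an estimated correlation); Ccn2 was 110-fold lower at 297.4. Cell cycle genes were lower for 12 and higher for 1 of 35, or 18 and 2 adjusted over the list alone (median -0.94, camera adjusted p = 6.09e-05, adjusted p = 0.22 with an estimated correlation), with the replication helicase gene Mcm5 down 4.80-fold.

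The keratinocyte, matrix and adipocyte lists were shifted up in the induced against the heart cells, with many members not called. Of 25 keratinocyte genes, 11 were higher and 2 lower, or 12 and 2 adjusted over the list alone (median 1.14, camera adjusted p = 0.000206, adjusted p = 0.36 with an estimated correlation), and Krt14, a basal keratin, measured 13468 against 1388. Of 40 fibroblast and matrix genes, 19 were higher and 4 lower, or 21 and 4 adjusted over the list alone (median 0.62, camera adjusted p = 7.21e-06, adjusted p = 0.44 with an estimated correlation); Col3a1, a fibrillar collagen gene, was 11.2-fold and Lox, the collagen cross-linking oxidase, 12.5-fold higher. Col3a1 read 9588 and 10007 on the arrays of induced preparation 1 and 24086 to 29048 on those of induced preparation 2. Adipocyte genes were higher for 10 and lower for 0 of 18, or 11 and 0 adjusted over the list alone (median 1.99, camera adjusted p = 1.8e-07, adjusted p = 0.2 with an estimated correlation), with the adipokine gene Adipoq 71.6-fold higher at 15072. Cholesterol synthesis genes were higher for 7 and lower for 0 of 16, or 8 and 0 adjusted over the list alone (median 1.00, camera adjusted p = 0.00014, adjusted p = 0.36 with an estimated correlation), with Insig1, a sterol-regulated gene, 3.12-fold higher. Gata4 and Hand2 were 4.36-fold and 10.2-fold lower, and Mef2c was 6.14-fold higher, by a probe whose alternative gave a log2 change of 1.51 (adjusted p = 0.02).

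Of the 17742 genes, 2997 were called (16.9%), 1483 higher and 1514 lower. The count was 1673 without heart preparation 1, 1422 without heart preparation 2 and 833 with fibroblast 7 and heart 3-3 as added preparations. It was 1633 when values were floored at 50, 4567 with the preparation as a random block and 6329 with each array as its own sample.

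**Figure D3:**
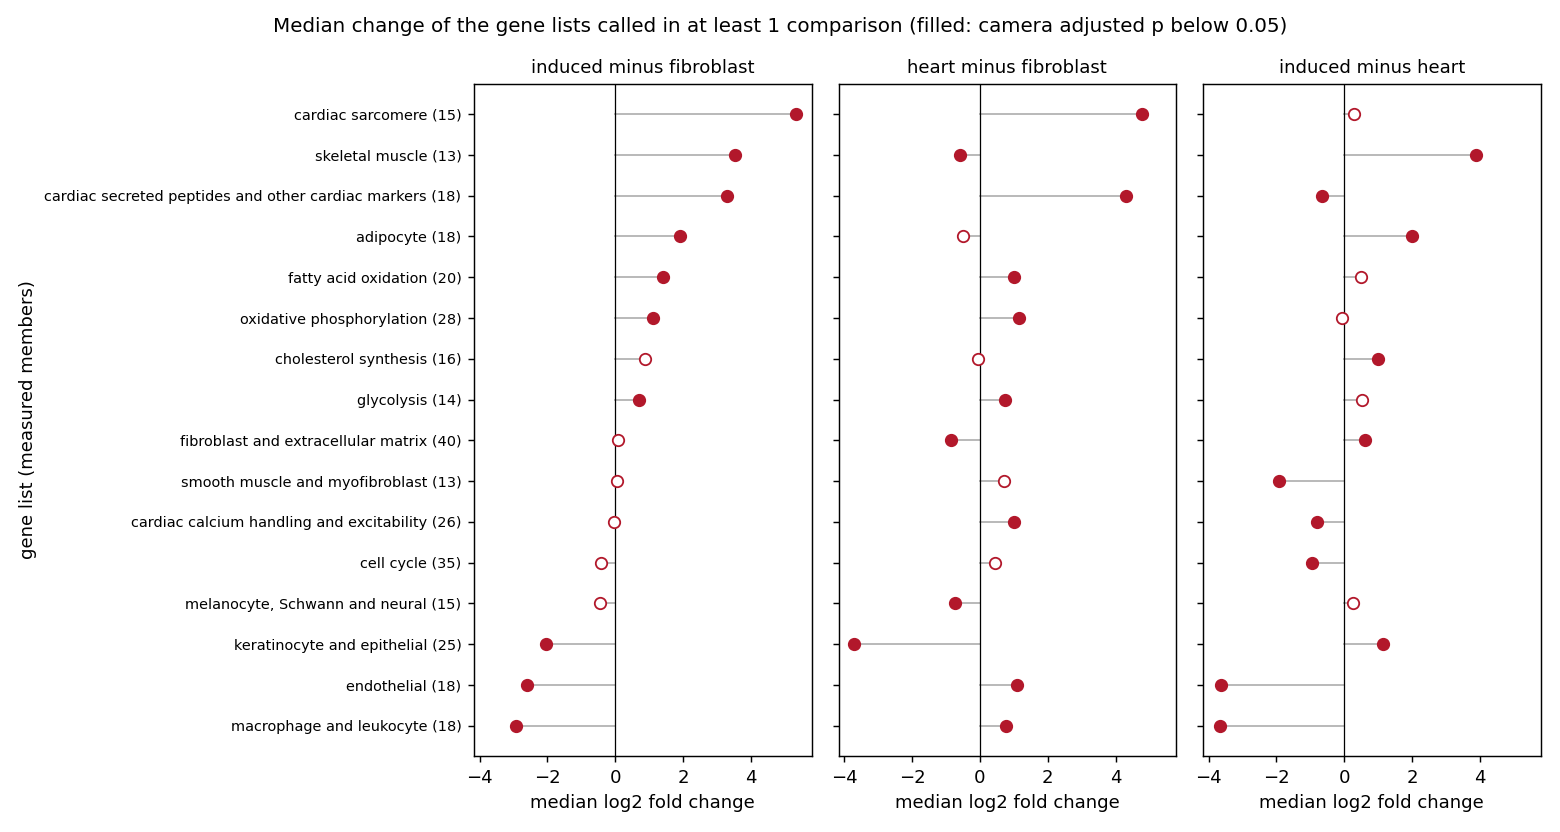
Median log2 fold change of each gene list called in at least 1 comparison, 1 panel per comparison, with the number of measured genes in brackets; filled points have a camera adjusted p under 0.05 with the preset correlation of 0.01. The skeletal muscle list has medians of 3.53, -0.59 and 3.88 in the panels from left to right.

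Most genes that set heart cells apart from fibroblasts lay on the same side in the induced cells. Of the 4259 genes higher in heart, 90.3% had a positive change in induced cells, 2861 were also called higher there (Ankrd1 and Smpx among them) and 140 were called lower, as was Nppa. Of the 4072 genes lower in heart, 91.6% had a negative change, 2678 were also called lower (Sfn and Krt17 among them) and 106 were called higher, as was Acta1. Independent lists would share 960 and 947, and simulated unchanged cells set against the same fibroblasts gave same-sign shares of 55.4% and 56.7% over 50 simulations. That simulation covers unchanged cells only, not cells that changed in a way unrelated to heart. The excess over it therefore does not by itself show a move toward heart cells. The simulated shares already include the effect of the shared fibroblast arrays. With 1 fibroblast preparation per comparison, so that none was shared, the shares were 91.7% and 91.2% one way round and 86.3% and 90.9% the other. These values argue against the shared arrays as the source of most of the excess. The median ratio of the change in induced cells to the change in heart cells was 0.83 for genes higher and 0.80 for genes lower in heart. Among the genes higher in heart, 743 were called short of the heart level in induced cells (Pln, Tnni3 and Nppa among them) and 226 beyond it; among those lower in heart the numbers were 658 and 105.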

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

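The tests of a wrong label and of time in culture were chosen after the similarity of fibroblast 7 had been seen, while the test of a mixture was set before its result was known.

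Values were searched for an array far from the others of its group, with the gap to its neighbour divided by the range of the group. Over 66 such groups of values, 9 had an array beyond the 95% limit, where chance gives about 1 in 20, and fibroblast 7 was that array in 8 of them. Its correlation with the mean of the other fibroblast arrays was 0.850 against 0.960 to 0.975 for the others (gap of 0.887 of the range). Actc1 stood at 34589 on it against 286 to 354 (0.956), and Tnnt2 at 15507 against 190 to 385 (0.840). Nppb stood at 300 against 939 to 1639 (0.672), Mef2c at 6199 against 570 to 1250 (0.671), and Atp2a2 at 4794 against 800 to 1466 (0.662). Gja1 stood at 20476 against 54846 to 65433 (0.848), and S100a4 at 13582 against 19804 to 25977 (0.582).

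Among the 2701 genes called with at least a 4-fold difference between induced cells and fibroblasts, fibroblast 7 lay nearer to the induced mean for 97.4%, against 97.7% to 99.3% for the induced arrays and 1.1% to 1.9% for the other fibroblast arrays. The fitted arrays served to choose these genes, which builds in much of their own shares, whereas fibroblast 7 took no part in the choice. A mixture of both RNAs is argued against by 67 genes bright in fibroblasts and dim in induced cells, which gave a fibroblast share of 0% on fibroblast 7. A time of 8 days in culture is shared by title with fibroblast 1, which lay nearer to the induced mean for 1.9% of the 2701 genes. That share cannot decide, since fibroblast 1 helped to choose the genes. Over all probes fibroblast 1 correlated at 0.969 with the other arrays of its preparation and at 0.853 with induced preparation 1. These values argue against time in culture, though on 1 array only. RNA of induced cells under a fibroblast label is the candidate explanation left by the 97.4%, as a hypothesis found and tested on the same data. Apart from time in culture, no biological explanation was tested.

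Vim stood at 65098 on heart 3-3 and at 65479 on the 4 other heart arrays (gap of 1 of the range), all of them at the saturated end of the scale. Among the 6046 probes without a gene symbol, which no comparison of genes used, 640 were called higher in induced cells than in fibroblasts, 590 of them at least 2-fold, and 1536 were called lower.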

How the results depend on the processing

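The floor of 50, the separate use of heart arrays 1-1 and 1-2, the removal of probes near 0 in 1 group and the crossed pairing were chosen after the data were seen; all other alternatives were planned. Of 115 recomputed gene counts, 103 stayed within 1.5 times the reported one. With fibroblast 7 and heart 3-3 as added preparations of their labelled groups the counts were 5 (100% higher) for induced cells against fibroblasts, 2133 (55.0% higher) for heart cells against fibroblasts and 833 (45.0% higher) for induced against heart cells. The last comparison also moved to 6329 with each array as its own sample, 4567 with the preparation as a random block (correlation of repeat arrays 0.38) and 1633 with a floor of 50. Leaving out 1 preparation, the lone one left being assumed to vary like the others, gave 4539 (without fibroblast preparation 2) to 7800, 4649 (without fibroblast preparation 2) to 9437 and 1422 (without heart preparation 2) to 3363 genes; leaving out 1 array gave 7537 to 8232, 7829 to 8517 and 2714 to 3056. Quantile normalization gave 8121, 8328 and 2985, but had little to change, since the deposited arrays already share nearly 1 distribution.

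The preparation numbers do not pair the samples: deviations of same-numbered preparations correlated at -0.03 between fibroblasts and induced cells, -0.04 between fibroblasts and heart cells and -0.21 between induced and heart cells. The replicate block gave 7478, 7773 and 2518 genes and 10, 12 and 13 called lists, the 2 added ones being cardiac transcription factors and fatty acid oxidation for induced against heart cells (adjusted p = 0.0481 each, 0.0583 without the block), and the crossed pairing of induced and heart preparations gave 2860.

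The share of heart genes on the same side in induced cells was 90.3% of those higher and 91.6% of those lower in heart. It moved by more than the SD between induced preparations in 19 of 24 recomputed values. That SD rests on 2 preparations and was 0.05 points for the higher and 0.47 for the lower genes, so small changes count as moves. The share was 88.3% and 89.5% with fibroblast 7 in fibroblast preparation 1. It was 89.9% for the higher genes without the dimmest probes, and 91.3% and 92.2% with a change of at least 2-fold besides. With the fibroblast preparations split it was 91.7% for the higher genes, and 86.3% and 90.9% the other way round. Without 1 preparation it ran from 86.3% to 92.5% and from 89.9% to 94.3%. The median ratio of changes moved further with the split, to 1.01 and 0.97 one way and 0.60 and 0.55 the other.

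Gene list calls numbered 0, 0 and 0 with an estimated correlation, where every called list lost its call, and 18, 14 and 14 with fry, which does not compare a list with other genes; without 1 preparation they numbered 10 to 11, 8 to 13 and 10 to 13. Of 429 recomputed single lists, 374 kept their call and 55 lost it. Of 1722 values of named genes, 1646 were the same, 53 lost and 6 gained a call, 13 changed sign without a call either way, and 4 reversed, all through another probe: Atp2a2 gave -0.10, -0.32 and 0.22 in the 3 comparisons and Hk1 gave -0.40 for heart cells against fibroblasts. A further Atp2a2 probe kept the direction (4.18, 6.16 and -1.98). The cause was not tested for any of these changes. Signal over background limits the dim genes, as repeat arrays differed by a median SD of 0.55 between intensities of 25 and 50.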

Other observations

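The genes of this and the next paragraph other than Lcn2 were chosen after their values were seen, as were all tests reported here except that of the other probes of genes near 0. The list of cardiac transcription factors was not called in any comparison (camera adjusted p = 0.675, 0.312 and 0.0583; 0.0481 for the last with the preparation number as a replicate block), with 2 of 19 members higher and 9 lower in induced than in heart cells. Gata6, a factor of heart and endoderm, measured 2403 in fibroblasts, 1638 in induced and 26918 in heart cells, a log2 change of -4.04 between induced and heart cells (adjusted p = 5.39e-05). Tbx20, a factor of heart chambers, measured 39, 35.1 and 165.3, while Isl1, a factor of cardiac progenitors and motor neurons, measured 81, 613.1 and 52.4. The epicardial genes Wt1 and Upk1b stood at 41.2 and 115.7 in induced cells against 1038 and 2144 in heart cells. As a list the epicardium genes were not called for heart cells against fibroblasts (camera adjusted p = 0.0601) or for induced against heart cells (0.0922), nor for induced cells against fibroblasts, where 2 of 13 were higher and 1 was lower.

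Of 22 cytokines and matrix proteases, 5 were higher and 11 lower in induced cells than in fibroblasts. Lcn2, an iron-binding protein of inflammation, rose 239-fold against fibroblasts to 14761, and the protease gene Mmp3 and the acute phase gene Hp rose 27.2-fold and 29.8-fold. Saa3, another acute phase gene, fell 11.2-fold, and the chemokine gene Ccl20 fell at least 5.98-fold to 10.6. The list was not called in any comparison (camera adjusted p = 0.202, 0.397 and 0.758), and its median of -0.45 and mean of 0.26 against heart cells differ in sign.

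The skeletal muscle and sarcomere genes that were higher in the induced cells invite a comparison of genes by the muscle that uses them. Of 30 listed genes shared by heart and skeletal muscle, 23 were measured. Of the 23, 22 were called higher in induced cells than in fibroblasts (median 5.33), the exception being Mb. Of 18 listed genes largely restricted to heart, 12 were measured. The 12 had a median of -0.86, with 1 higher (Tnni3, under 50) and 5 lower. Only 8 of the 12 were higher in heart cells than in fibroblasts, and Corin, Irx4 and Gata4 among the 5 were not. Corin and Irx4 are named outside the rule. Carried-over heart cells are argued against by Kcnj5, Nppa, Pln and Tnni3, which gave a median heart share of 0% where Actc1 alone would give 115%. The 61 keratinocyte, endothelial and macrophage genes had a median of -2.54 against fibroblasts. The fibroblast arrays other than fibroblast 7 held such transcripts themselves, with Krt14 at 59689 to 65050. A fall from that level cannot decide whether skin tissue was carried over. RNA of skeletal muscle cells is a candidate explanation that the -0.86 leaves open; Acta1, Tnni2 and Tnnc2 stood at 1207 to 1943 in the fibroblasts already, above the heart level. Whether such cells were carried over from the skin or arose by the induction was not tested, and neither was a partial cardiac program in the induced cells.

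Some probes lay near 0 in 1 group, with a mean of 10 or less, and at 200 or more in both others: 7 in fibroblasts, among them Irf2 and Ckmt2, and 8 in heart cells, among them Serinc1 and Csnk1a1. Absence of the transcript in that group is argued against for the 3 genes with another usable probe, whose 4 other probes were all higher in the group at 0 than in the others, by a median log2 difference of 0.80 (0.15 to 3.34). For failure of the probes on some arrays, nearness in probe number was examined. Of the 15, 4 had another such probe within 100 probe numbers, against 0.51 in random draws (permutation test over 10000 draws, p = 0.021). These were Irf2 with Tmem104, and Nbr1 with Serinc1. Positions on the array were not given, so nearness in probe number cannot show that probes failed. For the 12 probes whose gene has no other usable probe, the explanations cannot be told apart. On fibroblast 7, whose RNA is in doubt, Ckmt2 read 5617, Sh3bgr 630 and Irf2 146, so these probes gave signal there. Tmem104 read 0 on fibroblast 7, against 210 to 322 on the induced arrays that it otherwise resembles. Readings on 1 such array do not decide between the explanations. The Mocs2 probe, near 0 in heart cells, also read 11 on induced 1-3 against 9458 on its repeat array 1-8. That probe can thus drop on a single array, which does not decide its heart values.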
